A study of Mus musculus with 2 samples.

How the data were processed

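RNA from BCR-ABL-expressing Ba/F3 cells treated with imatinib was measured on 2 mouse Gene 1.0 ST arrays, 1 from cells grown with interleukin-3 (IL-3) and 1 from cells grown without it. Per the labels' protocols, RNA was isolated with a Qiagen miRNeasy kit, converted to sense-strand cDNA with the Ambion WT Expression kit, labelled with biotin and hybridised as 1 colour per array. The groups were taken from the sample titles. The label of the array titled with IL-3 is not uniform: its title and source name give IL-3, whereas its description says that the cells were grown without it. The source name of the other sample can also be read as without imatinib, although the treatment protocol gives imatinib for both.

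The values are the authors' processed values, deposited as 1 number per probe set and array for 28815 probe sets. As deposited, the values had been put on a log scale, taken here as log2, and made relative to a baseline of each probe set by the authors, as the values themselves show. The columns had medians of -0.03 with IL-3 and -0.05 without IL-3 and were correlated across probe sets (Pearson r 0.77). In 1760 probe sets (6.11%) the 2 values were equal and opposite, their sum lying within 1e-05 of 0, against 1 probe set with a sum between that tolerance and its double. A baseline set at the median of an even number of arrays gives this wherever these 2 arrays are the middle pair, so the baseline drew on further arrays, which are not analysed here. The summarisation method, background correction, normalization, log base and arrays behind the baseline are not given in the sources used here. Because the baseline is subtracted per probe set, the values carry no expression level, and no statement about detection or abundance was possible. The difference between the 2 arrays cancels the baseline and was used throughout as with IL-3 minus without IL-3. A higher value was read as higher expression; this direction is not stated in the sources either. If the values are natural logs or log10, the folds printed here are too small.

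Probe sets were named through the platform annotation, in which 21780 probe sets had 1 gene symbol, 1605 had several and 5430 had none. Probe sets with several genes were not named. Of those with 1 gene, 21689 had an identifier in the RefSeq gene table of GRCm38.p6, and 0 symbols needed updating. Where several probe sets named a gene, the one with the highest mean of both arrays was used, which gave 19935 genes.

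With 1 array per group there is no replicate, so no test, standard error or p-value between the conditions could be computed, and the number of arrays limits the precision. Genes were counted by a fixed rule, a log2 difference of at least 1 in size (2-fold). Among 998 genes with more than 1 probe set, the difference varied between probe sets of the same gene with a pooled SD of 0.14. This SD covers measurement within these arrays only, and some of those probe sets are near-identical, so it is a lower bound on the error. The design fixed before the data were examined assumed expression levels and filtered on each array's median; that filter has no meaning as a level filter on baseline-relative values, so no filter was applied in the values reported, and the filter as fixed was kept as an alternative.

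Before the data were examined, 28 gene lists were fixed from textbook knowledge: immediate early genes, mitogen-activated protein kinase (MAPK) feedback genes, STAT5 and cytokine-induced genes, pro-survival and pro-apoptotic BCL2 family members, FOXO and p53 targets, ribosome biogenesis and MYC targets, ribosomal proteins, G1/S and G2/M genes, cholesterol synthesis, glycolysis, ATF4 and amino acid genes, endoplasmic reticulum stress, heat shock, NF-kB targets, interferon-stimulated genes, autophagy and lysosome genes, IL-3 receptor components, histones, and markers of B-lineage cells, mast cells and basophils, macrophages, granulocytes, T cells, erythroid cells and fibroblasts. Of their 451 symbols, 407 were measured by a probe set naming that gene alone. The list called IL-3 receptor holds signalling components, such as Jak2 and Stat5b, beside the receptor chains. Each list's median difference was placed among the medians of 10000 random lists of the same size, matched in 20 bins on the mean deposited value because no expression level was at hand. A list was said to lie outside the random lists when its median fell below the 2.5 or above the 97.5 percentile. This describes these 2 arrays and is not a test between conditions. About 1.4 of the 28 lists would lie outside by chance if genes differed independently of each other. Members of a list can vary together between any 2 arrays, so more lists could lie outside without an effect of IL-3. The immediate early and MAPK lists were not blind choices, since published work on growth factor rescue from imatinib had singled out Fos and Dusp1.

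The genes named are the 15 with the largest difference in each direction, leaving out predicted genes, small RNAs and receptor gene families, up to 4 members of each list with the largest differences, any member of the BCL2, IL-3 receptor and cell marker lists, and Fos and Dusp1. Any other gene named was chosen after its values were seen, as stated there. The scripts were tested on simulated differences for the comparison of the 2 arrays over 19935 genes. The size rule counted 96.0% of genes given a 3-fold change and 52.0% of those given a 2-fold change. The scatter added to these changes was drawn from the observed differences below 2-fold between these same 2 arrays, with random signs. For a 2-fold change, a share of this order follows from the random signs. Scatter between cultures and larger observed differences were not included, so these shares are not the sensitivity of the comparison. Of 100 unchanged lists, 6 fell outside the random lists. The simulated differences were drawn independently for each gene. They check the scripts and do not show how lists whose members vary together behave between 2 arrays. Alternatives were quantile normalization of the columns, median centring, subtraction of a loess trend (span 0.3) of the difference on the mean deposited value, 3 filters on the deposited values, other rules for choosing a probe set, other sizes, unmatched random lists, members in no other list, and means in place of medians. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used. No genome coordinates are given because the sources used here do not say which build the array's values rest on; the RefSeq table was used for names only.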

Results

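The series compared gene expression in Ba/F3 cells that were due to survive imatinib with that in cells due to die from it. Ba/F3 is a mouse pro-B-like cell line that depends on IL-3, and BCR-ABL is the fusion kinase of chronic myeloid leukaemia, which frees these cells from that need. Imatinib inhibits the ABL kinase. Cells carrying BCR-ABL were grown in medium with 10% serum, with or without IL-3, and were treated with imatinib at 5 µM for 6 h per the treatment protocol. The submitters described cells without IL-3 as sensitive and cells with IL-3 as resistant. Each condition had 1 array, both titled as live cells, so every difference below compares 2 arrays, with no replicate error. The values of the 2 arrays were log values, taken as log2 because no log base is given, relative to a common per-probe-set baseline that is not given, and differences are with IL-3 minus without IL-3. The direction follows the sample titles, with the conflict in the labels described under the processing.

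The medians of the cell cycle, ribosome biogenesis, glycolysis, cholesterol synthesis, and ATF4 and amino acid lists lay above those of random lists. Most of their members were above 0. The medians of the immediate early, NF-kB, autophagy and lysosome, IL-3 receptor and signalling, and mast cell lists lay below. Most of their members were within 2-fold. Of 19935 genes, 88 (0.44%) were at least 2-fold higher with IL-3 and 131 (0.66%) were at least 2-fold lower. The lower genes included 17 with a difference of at least 4-fold, and the higher genes included 0. The split depended on the scaling. The higher genes made up 40.2% of the counted genes on the deposited scale and 37.9% after median centring (83 higher, 136 lower). They made up 27.8% after quantile normalization (62 higher, 161 lower) and 12.4% after a loess trend was subtracted (29 higher, 205 lower). With the sign turned these shares would be 59.8%, 62.1%, 72.2% and 87.6%. When both arrays had to reach their median the counts were 73 and 48, and if the values are natural logs they were 419 and 375. Over all genes the differences had a median of 0.04 and a robust spread (scaled median absolute deviation) of 0.17. From the lowest to the highest 25% of probe sets by mean deposited value, this spread was 0.16, 0.11, 0.13 and 0.41. A 2-fold difference thus stood out less from the scatter in the highest 25%. All 15 counted genes that had more than 1 probe set differed in the same direction in every one of them.

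Among the 15 genes with the largest differences on the side higher with IL-3, Ccnb1ip1, a ubiquitin ligase known from meiotic recombination, was 3.90-fold higher (1.84 with IL-3 against -0.12 without). Rrm2, the regulatory subunit of ribonucleotide reductase, was 3.17-fold higher (2.12 against 0.46), and Gins1, a subunit of the replicative helicase complex, was 2.90-fold higher. Mthfd2, a mitochondrial enzyme of one-carbon metabolism, was 2.99-fold higher, and Ctps, which makes CTP, was 2.54-fold higher. Hrob, a replication and repair factor, was 2.66-fold higher. Haus1 and Nek6, both linked to the mitotic spindle, were 1.49 and 1.38 higher on the log2 scale. Other genes of this side were Etv5, an ETS transcription factor downstream of ERK, at 2.80-fold, Fcgr1, the high-affinity IgG receptor, at 2.98-fold, Anxa2 at 2.70-fold, the pyrophosphatase Ppa1 at 2.61-fold, the mitochondrial protein Cisd1 at 2.54-fold, the fatty acid-binding protein Fabp5 at 2.53-fold and the protease inhibitor Serpinb1a at 2.51-fold.

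Among the 15 genes on the side lower with IL-3, Ngp, a neutrophil granule protein, was 7.31-fold lower (-2.15 with IL-3 against 0.72 without). The eosinophil granule genes Prg2, Ear6 and Epx were 6.77-fold, 4.73-fold and 4.25-fold lower; Ear6 belongs to a family of near-identical ribonuclease genes, so its value may mix family members. Fcer1a, the IgE receptor alpha chain of mast cells and basophils, was 5.49-fold lower (-0.58 against 1.88). The chemokine gene Ccl3 was 4.45-fold lower, the lectin-like receptor gene Olr1 4.72-fold lower, and Gpr183, an oxysterol receptor, 4.01-fold lower. Muc6, a gel-forming mucin, was 6.00-fold lower, the actin-severing gene Scin 4.76-fold lower, the embryonic globin gene Hbb-y 4.60-fold lower, and Far2 4.01-fold lower. Igsf6 completed these 15 genes with the smallest difference among them. Dusp1 and Fosb were also among them.

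**Figure D1:**
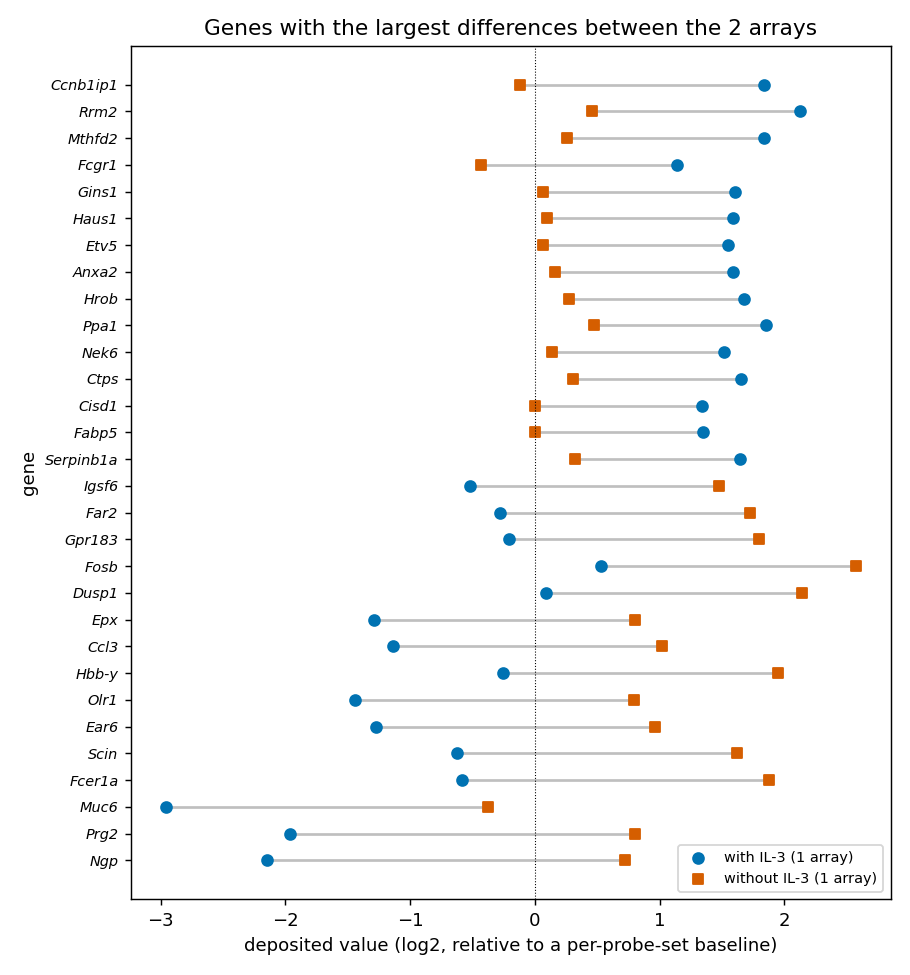
Deposited value of the 15 named genes with the largest difference in each direction (vertical axis) on the log2 scale relative to a per-probe-set baseline (horizontal axis); blue circles are the array with IL-3, orange squares the array without, and the grey line joins them. The genes lower with IL-3 span the wider differences, up to -2.87 for Ngp, against 1.33 for Serpinb1a to 1.96 for Ccnb1ip1 on the other side.

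Of the 28 fixed gene lists, 6 lay above the matched random lists, 5 lay below and 17 lay within them. Filters on the deposited values keep or drop members partly through the difference itself, because the values are relative to a baseline, so list values under a filter show how far the result depends on it and not a better estimate. The G1/S list had the median farthest above 0; a turned sign or swapped labels, which the sources leave open, would place it farthest below and the autophagy and lysosome list highest. All but 1 of its 26 measured members were above 0, 10 of them at least 2-fold and 0 at least 2-fold lower, with a median difference of 0.75, above the central 95% of random-list medians (-0.05 to 0.32). Besides Rrm2 and Gins1, Ccne1 (cyclin E1) was 2.33-fold and Tk1 (thymidine kinase) 2.32-fold higher. All 21 measured G2/M genes were above 0, with a median of 0.53 (random lists -0.08 to 0.37), and the mitotic kinase genes Bub1, Aurkb, Aurka and Plk1 were 2.31-fold, 2.04-fold, 1.83-fold and 1.76-fold higher. With the loess trend subtracted, 3 G1/S genes and 0 G2/M genes were at least 2-fold higher, although 24 of 26 and 21 of 21 members still had a difference above 0.

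Ribosome biogenesis and MYC target genes were higher as a list, with a median of 0.65 (random lists -0.08 to 0.34) and 23 of 25 members above 0. The difference was moderate for single genes, since 15 members were at least 1.5-fold higher and only Ranbp1, a cofactor of nuclear transport, passed 2-fold (2.20-fold). Odc1 and Srm, enzymes of polyamine synthesis, were 1.96-fold and 1.90-fold higher, and Cad, which starts pyrimidine synthesis, was 1.90-fold higher. With the loess trend subtracted, 0 members passed 2-fold. The ribosomal protein genes themselves were not higher: their median was -0.08 (percentile 4.2, or 0.9 among unmatched random lists), with 17 of 24 measured and Rpl5 at -0.32, Rpl13 at -0.20, Rpl10a at -0.19 and Rps14 at -0.17. Ribosomal protein genes have many processed pseudogenes, so that these values are uncertain.

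Metabolic lists were also higher with IL-3. In the glycolysis list, 15 of 17 members were above 0, with a median of 0.35 (percentile 99.3); the glucose transporter gene Slc2a1 was 2.34-fold higher, the phosphofructokinase gene Pfkl 1.98-fold, Pgam1 1.88-fold and the lactate dehydrogenase gene Ldha 1.82-fold. The cholesterol synthesis list had 14 of 16 members above 0 and a median of 0.31 (percentile 99.1), with 0 members at 2-fold; Sqle, Nsdhl, Idi1 and Fdps were 1.58-fold, 1.52-fold, 1.51-fold and 1.43-fold higher. In the ATF4 and amino acid list (24 members, median 0.25, percentile 99.4), 18 members were above 0 and 6 were below. Atf4 itself differed by 0.09 and Ddit3 by -0.36, both named after their values were seen. In this list, 4 members were at least 2-fold higher. These were Mthfd2, the serine synthesis genes Phgdh (2.31-fold) and Psat1 (2.27-fold), and the asparagine synthetase gene Asns (2.17-fold), which was named after its value was seen to complete this count. Slc7a11, the cystine transporter gene of the same list, was 2.41-fold lower. With the loess trend subtracted, 2 genes of the ATF4 list and 0 of the glycolysis list were at least 2-fold higher. The glycolysis list moved to percentile 97.4, just within the random lists, after quantile normalization, which gave a median of 0.22, and the cholesterol synthesis list also moved to 97.4 when both arrays had to reach their median. Under the filters on the deposited values the glycolysis median reached 0.68 and the ATF4 median 0.52.

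Immediate early genes, which mitogens and stress induce within minutes, had a list median of -0.11 (26 members, percentile 0.1), with 18 members below 0, several by less than the probe set SD of 0.14. The mean was -0.37, and the median was between -0.31 and -0.72 under the filters, a size that follows from keeping members high in an array. The list held 5 members at least 2-fold lower and 0 at least 2-fold higher. Fosb was 4.12-fold lower (0.53 with IL-3 against 2.57 without), Klf6 2.78-fold, Fos 2.05-fold and Btg2 2.03-fold lower. Zfp36, which encodes an mRNA-decay factor, differed by -1.32. Published work on growth factor rescue from imatinib singled out Fos and Dusp1 as induced by growth factor, which is opposite to the direction read here from the sample titles. In the MAPK feedback list, genes went both ways: Dusp1, a phosphatase that inactivates MAP kinases, was 4.14-fold lower (0.09 against 2.14), whereas Etv5 was 2.80-fold higher, Spred2 1.88-fold higher and Dusp4 1.60-fold higher. That list had a median of 0.12 (16 members, percentile 81.0) and lay within the random lists, but at percentile 98.7 when both arrays had to reach their median.

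The STAT5 and cytokine-induced list also lay within the random lists (13 members, median 0.16, percentile 91.8; 97.6 among unmatched random lists). The survival kinase genes Pim2 and Pim1 were 1.80-fold and 1.68-fold higher with IL-3, and the cyclin gene Ccnd2 was 1.42-fold higher. The cytokine gene Osm was 2.31-fold lower. The median of the IL-3 receptor and signalling components lay below the random lists (13 members, median -0.20, percentile 0.3), with small differences that ranged from -0.43 for Il3ra, the IL-3 receptor alpha chain, to 0.38 for the phosphatase gene Ptpn6; Csf2rb, the common beta chain, differed by 0.06 and Abl1 by -0.26. This list moved to percentile 4.1, within the random lists, under the filter at percentile 67, and its mean was -0.11.

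None of the 10 of 11 pro-apoptotic and 4 of 7 pro-survival BCL2 family genes measured here differed by 2-fold. Among the pro-apoptotic members, Bcl2l11, which encodes BIM, was 1.62-fold lower with IL-3, Bad was 1.29-fold lower and Bak1 1.24-fold higher. Bbc3 and Pmaip1, which encode PUMA and NOXA, differed by 0.01 and -0.15. The list median was -0.03 (10 members, percentile 12.5). Of the pro-survival members, Mcl1 differed by -0.32, Bcl2 by -0.23, Bcl2l1, which encodes BCL-XL, by 0.16 and Bcl2l2 by -0.05 (4 members, median -0.14, percentile 12.1).

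Autophagy and lysosome genes were below 0 in 13 of 15 members, with a median of -0.35 (percentile 0.0) and 0 members at 2-fold. The cathepsin gene Ctsd was 1.80-fold lower, the sialidase gene Neu1 1.74-fold, the autophagy receptor gene Sqstm1 1.59-fold and Gla 1.44-fold. The FOXO target list had a median of -0.04 and lay within the random lists (19 members, percentile 5.7), but at percentile 0.2, 0.9 and 0.0, below them, under the 3 filters on the deposited values, with Txnip 1.96-fold, Pik3ip1 1.55-fold and the cell cycle inhibitor gene Cdkn1b 1.54-fold lower. The p53 target list likewise lay within the random lists (16 members, median -0.03, percentile 11.8), with Trp53inp1 2.99-fold, Btg2 2.03-fold and Fas 1.47-fold lower. Sesn2 was 1.27-fold higher, and 6 of the 16 members were above 0. NF-kB targets had a median of -0.08 below the random lists (17 members, percentile 1.1), where Ccl3 and Il6, at 2.21-fold lower, were the 2 members past 2-fold. Nfkbia was 1.64-fold lower and Il1b 1.35-fold higher, and 6 of the 17 members were above 0. Under the filters the NF-kB median was -0.22 to -0.24, and the list moved to percentile 4.3, within the random lists, under the filter at percentile 67. The interferon-stimulated list had a median of -0.05 (18 members, percentile 4.9), with Irf7 1.91-fold, Oasl2 1.57-fold and Usp18 1.51-fold lower. That list lay below the random lists after quantile normalization (percentile 1.7) and under the filter fixed before the data were examined and the filter at percentile 67 (percentile 0.0 in both).

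The remaining stress and histone lists lay within the matched random lists. Endoplasmic reticulum stress genes had a median of 0.22 (14 members, percentile 87.6, or 99.9 among unmatched random lists), with Dnajb9 1.86-fold lower but Sdf2l1 1.77-fold and Creld2 1.70-fold higher. Heat shock genes had a median of 0.13 (10 members, percentile 66.1); the mitochondrial chaperone gene Hspd1 was 2.24-fold higher and Hsp90aa1 1.61-fold higher. The histone list had a median of -0.11 (6 members, percentile 8.4, or 1.4 under the filter fixed before the data were examined), with the linker histone gene H1f2 3.39-fold lower.

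Markers of other cell types were examined beside these groups. The mast cell and basophil list lay below the random lists (15 members, median -0.09, percentile 0.7), and 3 members were at least 2-fold lower with IL-3, namely Fcer1a, the carboxypeptidase gene Cpa3 at 2.16-fold and the chymase gene Cma1 at 2.14-fold. The size of this list's median depended on the filter, which keeps members raised in the array without IL-3: it was -0.72 under the filter fixed before the data were examined, -0.92 under the filter at percentile 67, and the mean was -0.42. In the same list, Ms4a2 differed by -0.92, Il4 by -0.53, Hdc by 0.00, Mcpt8 by -0.09 and Tpsb2 by 0.19. Of the 15 members, 6 were above 0. B-lineage markers had a median of 0.05 (13 members, percentile 64.1), with Cd79a at -0.35 and Vpreb2 at 0.23. Macrophage markers had a median of 0.06 (11 members, percentile 71.2), with Adgre1 at -0.79 and Lyz2 at 0.24. Granulocyte markers had a median of 0.02 (11 members, percentile 43.0); Itgam, an integrin chain of myeloid cells, was 2.11-fold lower, whereas S100a9 differed by 0.38 and Mpo by 0.17. T cell markers (9 members, median 0.01, percentile 29.9), erythroid markers (5 members, median -0.06, percentile 14.7) and fibroblast markers (7 members, median 0.00, percentile 24.8) lay within the random lists, with Cd3g at -0.80. The mean and median had opposite signs in the B-lineage, macrophage, granulocyte and T cell lists, whose means were -0.003, -0.03, -0.03 and -0.05.

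**Figure D2:**
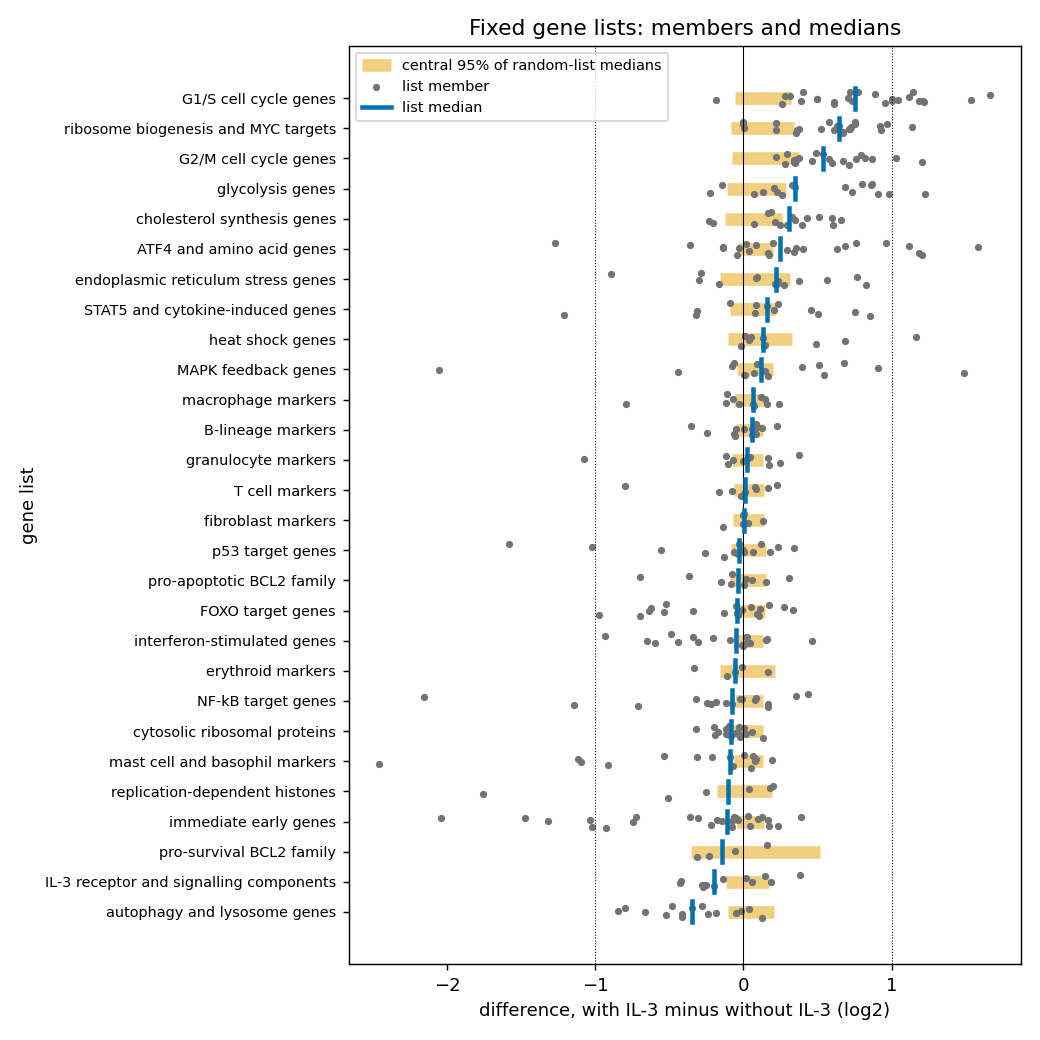
Difference between the arrays (log2, with IL-3 minus without, horizontal axis) for the 28 fixed gene lists (vertical axis); grey points are list members, the blue bar is the list median, the orange band holds the central 95% of medians of 10000 random lists, and dotted lines mark 2-fold. The G1/S, ribosome biogenesis and G2/M medians (0.75, 0.65 and 0.53) lie farthest to the right, and the autophagy and lysosome median (-0.35) farthest to the left.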

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

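Of the 5430 probe sets that the platform annotation leaves without a gene name, which enter no gene count or gene list above, 48 were at least 2-fold lower with IL-3 and 7 were at least 2-fold higher, with extremes of -2.83 and 1.38 on the log2 scale. On the deposited scale these shares are 0.88% lower and 0.13% higher, against 0.66% and 0.44% among named genes. The share past 2-fold was thus similar and the balance leaned more to the lower side, which was not tested. With the sign turned, 0.88% would be higher and 0.13% lower, against 0.66% and 0.44%. The balance also depends on the scaling: among counted named genes, the lower share was 59.8% on the deposited scale and 87.6% with the loess trend subtracted. The unnamed probe sets are listed because the gene counts and lists leave them out. Dixon's rule for single distant samples and the comparison of effects between groups need more than 1 array per group and could not be applied.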

How the results depend on the processing

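Among 148 genes of the naming rule, each that differed by at least 2-fold kept its direction under each scaling, filter and probe set rule that gave a value. Of 1066 values of the 148 genes, 70 moved by more than 0.14. Most of these values could not move, since a filter only keeps or drops a gene and a probe set rule changes only genes with more than 1 probe set. Under the loess trend, which can move every gene, 58 of the 148 genes moved by more than 0.14. The kept directions are therefore weak evidence of robustness. The counts of 88 higher and 131 lower genes became 29 and 205 with the loess trend subtracted, where all 29 and 131 of the 205 were shared with the deposited scale, and 48 lower genes remained when both arrays had to reach their median, a filter that removes genes low in 1 array by construction. They became 701 and 540 at 1.5-fold, 2 and 29 at 3-fold, and, in alternatives chosen after seeing the data, 419 and 375 if the values are natural logs and 2325 and 1679 if they are log10. The correlation of the arrays was 0.55 under the filter fixed before the data were examined. None of the 11 lists outside the random lists changed the sign of its median. The loess trend gave medians of 0.46 for ribosome biogenesis, 0.58 for G1/S, 0.37 for G2/M, 0.21 for glycolysis and 0.18 for ATF4 genes, and quantile normalization gave 0.22 for glycolysis. The filter fixed before the data were examined gave -0.31 for immediate early, 0.35 for ATF4, -0.22 for NF-kB and -0.72 for mast cell genes. Requiring both arrays to reach the median gave -0.31 for immediate early, 0.89 for G1/S, 0.51 for glycolysis, 0.52 for ATF4 and -0.22 for NF-kB genes, and the filter at percentile 67 gave -0.72 for immediate early, 0.68 for glycolysis, 0.38 for ATF4, -0.24 for NF-kB and -0.92 for mast cell genes. Means were -0.37 for immediate early, 0.49 for glycolysis, 0.34 for ATF4, -0.23 for NF-kB, -0.11 for IL-3 receptor and -0.42 for mast cell genes. Of 98 repeated placements of these 11 lists, 94 stayed outside on the same side; the exceptions were cholesterol synthesis (percentile 97.4, both arrays at the median), glycolysis (97.4, quantile normalization), and NF-kB (4.3) and IL-3 receptor genes (4.1) under the filter at percentile 67. Of 143 placements of the other 17 lists, 11 lay outside, among them 3 of FOXO targets and 3 of interferon-stimulated genes. Where the construction of a setting does not show it, the cause was not tested. No paired analysis was possible because each group has 1 array. The lack of replicates and of expression levels limits every value.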

Other observations

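All tests in this part except that of the eosinophil markers were chosen after the results were seen. The following genes were chosen after their values were seen, because of their large differences, and no list or enrichment test stands behind them. The chemokine genes Ccl6 and Ccl9 were 3.97-fold and 3.39-fold lower with IL-3, the C-type lectin genes Clec12a and Clec7a 3.24-fold and 2.95-fold lower, and the inhibitory IgG receptor gene Fcgr2b 2.90-fold lower, whereas Fcgr1, the activating receptor, was higher. Of 30 histone genes with a probe set of their own, 4 were at least 2-fold lower with IL-3 (H1f2, H3c4, H2bc4 and H2bc8, at 3.39-fold, 3.01-fold, 2.87-fold and 2.55-fold) and 0 were at least 2-fold higher, with a median of -0.06. These genes have near-identical copies, so their values are uncertain. On the other side, the mitochondrial protease gene Lonp1, the nucleotide kinase gene Nme1 and the haem synthesis gene Cpox were 2.22-fold, 2.26-fold and 2.20-fold higher with IL-3.

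The lower level of Fosb, Klf6, Zfp36, Fos and Btg2 with IL-3, beside higher proliferation genes, is the pattern that most needs a repeat. The median of these 5 genes, picked because each was at least 2-fold lower, was -1.32 on the deposited scale. It stayed at or below -1.34 under the 3 other scalings. Those scalings shifted the median of all genes by only -0.02 to -0.04, so they could hardly have removed differences of this size. The check therefore cannot decide whether the authors' own normalization, which is not given, had a part in the pattern. Swapped labels or a turned sign remain open, because the description of the array titled with IL-3 says that it had none. Fos (-1.03) and Dusp1 (-2.05) also ran opposite to the published work on growth factor rescue. The joint median of the G1/S and ribosome biogenesis lists was 0.67. Reading the labels from that value, or from Fos and Dusp1, would assume what IL-3 does. A general handling or stress response also could not be told apart, since the other 21 immediate early genes had a median of -0.065 and the heat shock list 0.13, while the lowest of those genes, Jun, named after its value was seen, was at -0.92. A difference between cells due to die and cells due to survive is the biological explanation that the design gives, and 1 array per group cannot test it.

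The lower myeloid genes with IL-3 (Ngp, Prg2, Epx, Ear6, Fcer1a) could come from other cells in the culture without IL-3 or from the Ba/F3 cells themselves. Relative to the baseline, Ngp (-2.15 with IL-3 against 0.72 without), Prg2 (-1.96 against 0.80), Epx (-1.29 against 0.80) and Ear6 (-1.27 against 0.97) lay farther from 0 with IL-3. Fcer1a lay farther from 0 without IL-3 (-0.58 against 1.88). The arrays behind the baseline are not given, so which of the 2 arrays is unusual for these genes is open. Neutrophils or macrophages would bring their other abundant transcripts. However, the joint median of 22 macrophage and granulocyte markers was 0.034, with S100a8 at 0.16, S100a9 at 0.38 and Lyz2 at 0.24. These values argue against neutrophils or macrophages as the whole source, although Itgam was at -1.08 and Adgre1 at -0.79. The standard error of the mean over these markers was 0.07, which describes scatter between genes and not between cultures. Eosinophils stay open: 6 further markers, listed before they were looked up, had a median of -0.17, ranging from -0.95 for Prg3 to 0.11 for Il5ra. The standard error of the mean over these markers was 0.17, again a scatter between genes only. Mast cells or basophils also stay open, and no prediction was set for them. Their list, which includes Fcer1a, was the only cell marker list below the random lists (median -0.09, percentile 0.7). It held 3 members at least 2-fold lower, whereas 6 of its 15 members were above 0. The labels call both samples live cells but name no sort for lineage. Myeloid gene expression by the Ba/F3 cells was not tested.

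The higher proliferation lists with IL-3 were set against a trend between the arrays. From the lowest to the highest 25% of probe sets by mean deposited value the median differences were 0.02, 0.03, 0.01 and 0.09, so only the highest bin stood apart. After a loess trend was subtracted, the joint median of the 72 G1/S, G2/M and ribosome biogenesis genes was 0.49, against 0.65 before. A trend along the mean deposited value thus did not account for the whole difference. The placement of these lists among random lists matched on that mean already implied this. That mean carries no expression level, so a trend along expression level could not be checked. Part of the size is consistent with the trend, and the biological difference in IL-3 remains an untested explanation with 1 array per group.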
